A study of Mus musculus with 4 samples.

How the data were processed

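The series holds bulk RNA-seq of whole epidermis from 2 WT and 2 Irx5KO mice at postnatal day 20. Per the labels, back skin was incubated in 0.25% trypsin for 2 h at 34 °C, the epidermis was separated mechanically and filtered to a cell suspension, and RNA with an integrity number above 8 was used for single-end Illumina sequencing. The labels name both a SMARTER and an Illumina kit for the libraries and give neither the sex of the mice nor the days of preparation. The design text counts 2 mice per genotype, so each library was taken as 1 mouse. The labels add nothing on litters, and the p-values measure the spread between these samples.

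The values are FPKM (fragments per kilobase of transcript, scaled to the mapped total), as deposited by the authors in 1 table with a column per sample. Per the submitters' processing notes, Bowtie2, DESeq2 and the build mm10 were used. The step from alignments to FPKM and the annotation are not given in the sources used here. The table holds 23847 rows under 23359 symbols. Of these, 256 symbols stand on more than 1 row (744 rows), 27 rows carry a date in place of a gene symbol and were kept in the fit without a name, and 828 rows are small RNA genes. Symbols were matched to GENCODE M21 (mm10) for position, transcript length and GC content, through older synonyms where needed, which placed 98.2% of the rows. Positions are 1-based. Strand-specific counting is not stated, so overlapping genes and close copies can share reads.

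Counts were not used here. Depth was estimated from the low values of genes with a single transcript of over 600 bases: with an assumed fragment of 200 bases, 64.9% to 67.3% of the low values of each library (up to 10 fragments) were whole within 0.1 of a fragment, against 20.0% by chance. The depth is therefore an estimate, and no count model was run.

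The design, the filter, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Rows with an FPKM of at least 1 in at least 2 of the 4 libraries were tested, 11643 in all. The test was limma on log2(FPKM + 1) with an intensity trend in the prior variance, 2-sided, with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. A fold change on this scale understates the change of genes of low level. An exact permutation of 2 against 2 libraries cannot give a p under 0.333, so no single gene has a permutation test here and all p-values rest on the model. In 5 simulations of this comparison with the real levels and spread, over 11643 rows with 200 changed, the test recovered 91.8% of changes of 1 and 100% of changes of 2 log2 units, and 8.59% of its calls were false. These simulated genes varied independently, without a shift or trend shared by a whole library, and far fewer rows changed than the 4200 called here. The share of false calls in the real comparison is therefore not known from them.

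Of 46 lists of pathway genes and cell type markers, the 33 with at least 5 tested members were tested with limma's camera (2-sided, preset correlation 0.01, adjusted over the lists), which asks whether a list moves relative to all other genes. A symbol on several rows entered with its row of highest mean. Beside it stand camera with an estimated correlation per list, camera on ranks, and fry, whose p tests whether the genes of a list move, on balance, one way, without comparing them with other genes. No list passed with an estimated correlation (lowest adjusted p = 0.524) or with fry (lowest adjusted p = 0.0730). In simulations of 5 lists of 20 genes shifted by 0.5 log2 units, camera with the preset correlation and on ranks called 5, fry 2 and the estimated correlation 0. Of 195 unshifted lists the preset correlation called 1 and the others 0. The simulated genes varied independently of each other, whereas the estimated correlations of the real lists ranged from -0.0614 to 0.958. The simulations therefore do not show how often the preset correlation calls lists of correlated genes falsely. Counts per list are given over all rows tested and adjusted over the list alone. The list of mitochondrially encoded genes matched 0 rows of the table.

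Genes named in the text are Irx5; the 12 rows with the largest positive and the 12 with the largest negative change among those past the threshold, with the libraries of one genotype all above those of the other and a mean of at least 5 FPKM in the higher; a panel fixed in advance (Irx3, Brca1, Fgf18, Cd34, Lgr5, Krt15, Shh, Mki67, Cdkn1a and Trp53); and up to 4 members of smallest p of each list described. Results for some genes that this rule would name are not reported. Exceptions are said to be such. No fold is given against a group listed at 0.

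Alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, scaling by the median of ratios, to a fixed sum (TPM), by quantiles or without the 100 most abundant rows, no trend, robust empirical Bayes, a log2 change of at least 1, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were 1 row per symbol, no small RNA rows, no X and Y genes, and removal of each library's trend on transcript length and GC content with its median kept. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.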

Results

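RNA of whole back-skin epidermis was sequenced from mice at postnatal day 20, with 2 wild-type (WT) libraries and 2 libraries from Irx5 knockout (Irx5KO) mice. Irx5 encodes a homeodomain transcription factor of the Iroquois family, and the title of the series ties it to DNA damage repair and to the activation of hair follicle stem cells. The comparison of Irx5KO with WT therefore asks which epidermal transcripts differ when Irx5 is disrupted, with repair, cell cycle and stem cell genes at its centre. The deposited FPKM values summed to 603270 and 538695 in WT replicates 1 and 2 and to 451080 and 511333 in Irx5KO replicates 1 and 2. Most low values fell near steps of whole fragments, from which the depth was estimated. At that depth an FPKM of 1 on a transcript of 2000 bases stands for 94.1 to 108 fragments. Replicates correlated more closely (Pearson r of log2 values across genes 0.977 within WT and 0.983 within Irx5KO) than libraries of different genotype (0.899 to 0.932). Values below are mean FPKM ± SD of n = 2 libraries, changes are Irx5KO minus WT on the log2(FPKM + 1) scale, and adjusted p-values are from limma.

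Irx5 transcript was lower in both knockout libraries but was still present. It measured 17.4 and 16.4 FPKM in WT replicates 1 and 2 and 10.01 and 10.08 FPKM in Irx5KO replicates 1 and 2, which is 59.5% of the WT mean (Irx5 log2 fold change -0.70, SE 0.162, adjusted p = 0.0117). The gene lies on mouse chromosome 8 at 92357625 to 92376286 (mm10). A value for the whole gene does not tell exons apart, so it shows neither which part was deleted nor whether the remaining RNA is coding, and the labels do not describe the allele. Leaving out either Irx5KO library ended the call, with an adjusted p = 0.103 without replicate 1 and 0.0899 without replicate 2, as did rescaling to TPM (adjusted p = 0.0577). Its neighbour Irx3, at 91798525 to 91802067 on the same chromosome, fell from 32.1 ± 0.714 to 13.6 ± 0.58 FPKM (-1.18, adjusted p = 0.00117). Other Iroquois genes moved the other way. Irx2 rose from 30.8 ± 6.58 to 101 ± 1.12 FPKM (1.70, adjusted p = 5.18e-04) and Irx1 from 7.05 ± 0.179 to 14.5 ± 2.33 FPKM (0.94, adjusted p = 0.00489). Of the 6 tested members of the list of Iroquois genes and Irx5 neighbours, 3 rose, 2 fell and 1 did not pass the test, with the same counts when adjusted over the list alone (camera adjusted p = 0.870). The counts were 3 and 1 without Irx5KO replicate 1 and 1 and 1 without Irx5KO replicate 2.

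The genotypes also differed in sex-linked transcripts, a difference that runs through every comparison here. Xist, the noncoding RNA of the inactive X chromosome, was at 35.3 ± 1.89 FPKM in WT and 0.0532 ± 0.0104 FPKM in Irx5KO (adjusted p = 5.07e-07). The Y-linked gene Eif2s3y was at 0.0386 ± 0.00506 FPKM in WT and 73.3 ± 3.42 FPKM in Irx5KO (adjusted p = 1.55e-07). Ddx3y (18.4 ± 1.98 FPKM in Irx5KO, adjusted p = 2.07e-06) and Uty (7.77 ± 0.0545 FPKM, adjusted p = 6.98e-06), also on the Y chromosome, were under 1 FPKM in WT. Kdm5d was listed at 0 in both WT libraries and at 9.07 and 6.33 FPKM in Irx5KO replicates 1 and 2. Both WT libraries thus carried a female pattern and both Irx5KO libraries a male pattern, and sex and genotype cannot be separated in this design.

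**Figure D1:**
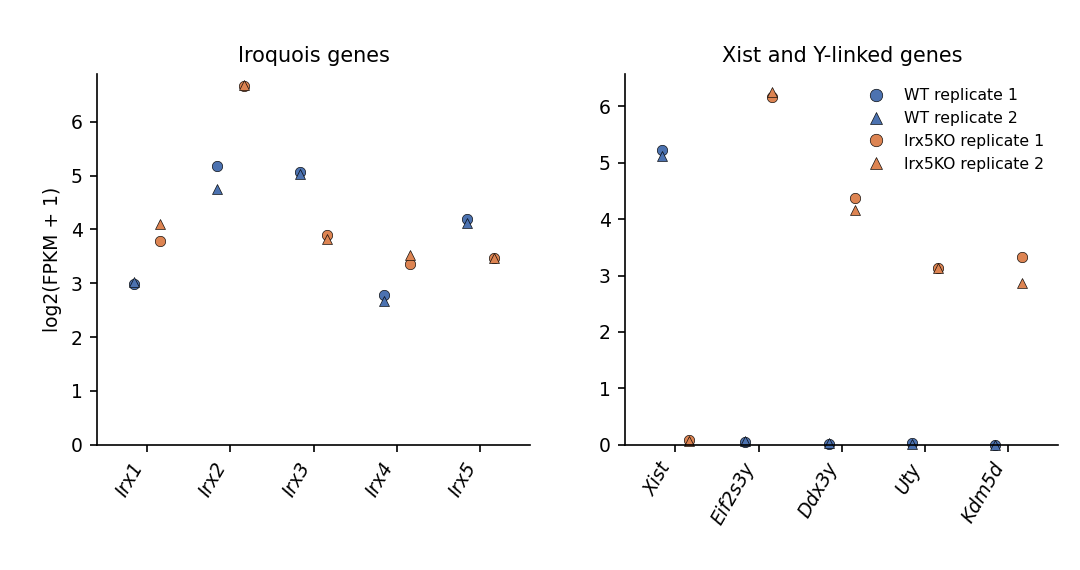
Level of Iroquois genes (left) and of Xist and Y-linked genes (right) as log2(FPKM + 1), with 1 point per library, circles for replicate 1, triangles for replicate 2, blue for WT and orange for Irx5KO. Irx5 and Irx3 were lower and Irx1 and Irx2 higher in both Irx5KO libraries, and the libraries of each genotype shared 1 sex pattern.

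Across the transcriptome, 3127 of 11643 rows tested were higher and 1073 lower in Irx5KO at an adjusted p below 0.05, so that 74.5% of the calls were increases. The median log2 fold change of all rows was 0.26, and this excess of increases depended on how the libraries were scaled. Scaling by the median of ratios, which moved that median to -0.00, gave 1226 higher and 1613 lower rows. Quantile normalization gave 1516 and 1313, rescaling to a fixed sum (TPM) 5577 and 875, and rescaling without the 100 most abundant rows 4796 and 947. With a log2 change of at least 1 as a further condition the deposited values gave 619 higher and 591 lower rows. The libraries of one genotype lay entirely above those of the other for 72.3% of the rows, against 33.3% by chance.

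**Figure D2:**
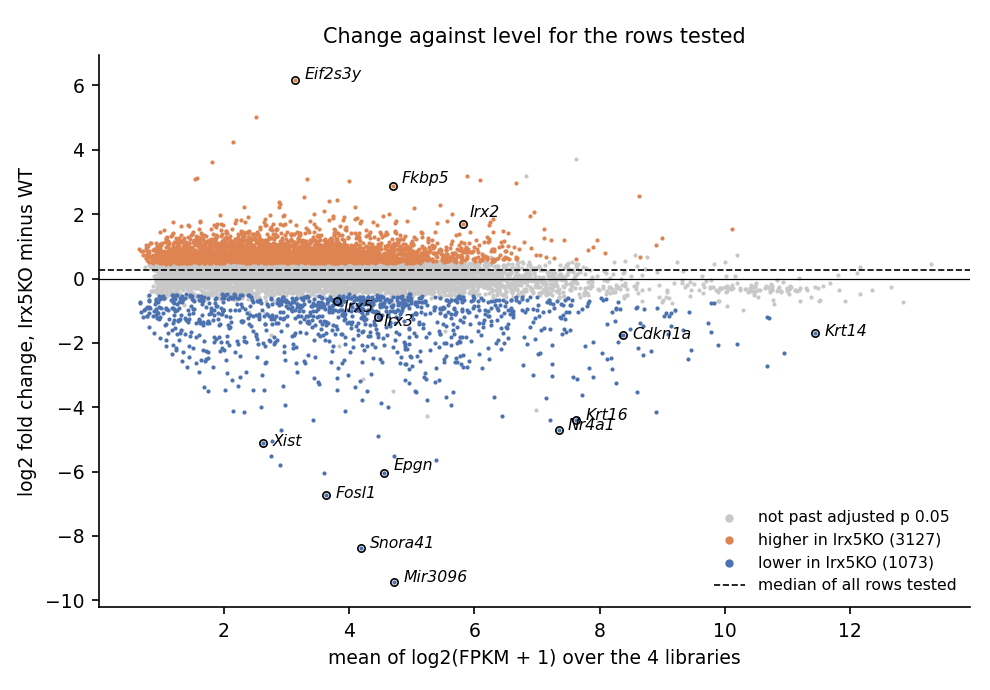
Log2 fold change (Irx5KO minus WT) against the mean of log2(FPKM + 1) over the 4 libraries, with 1 point per row tested, orange for the 3127 higher and blue for the 1073 lower rows. The dashed line marks the median of all rows at 0.26, and rows listed at 0 in 1 genotype lie where the added 1 places them.

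The 12 largest decreases mixed genes of growth factor signalling and of the acute stress response with small RNA, noncoding and pseudogene rows. Fosl1, an AP-1 subunit induced by growth factors, fell from 133 ± 58.8 to 0.206 ± 0.0219 FPKM (-6.73, adjusted p = 2.07e-06). Epgn, an epidermal growth factor receptor ligand, fell from 197 ± 68.2 to 1.95 ± 0.67 FPKM (-6.04, adjusted p = 2.89e-06), and Sprr1b, a cornified envelope precursor, from 101 ± 37.0 to 0.492 ± 0.0544 FPKM (-6.04, adjusted p = 2.07e-06). The orphan nuclear receptor Nr4a3 fell by 5.05 (adjusted p = 6.96e-06), the activity-induced gene Arc fell by 4.91 (adjusted p = 4.89e-05) and the interferon-inducible gene Ifi202b, a member of a family of close copies, fell by 5.65 (adjusted p = 1.89e-05). Ccdc85b fell by 5.51 (adjusted p = 2.30e-06), but it overlaps Fosl1 on chromosome 19 (5453180 to 5457894 against 5447547 to 5455946), so reads of Fosl1 cannot be ruled out of its value. The pseudogene row Atp6v0c-ps2 differed 114 to 17.0 FPKM between the WT replicates and was near 0 in Irx5KO. Xist was also in this group. Of the small RNA rows, whose FPKM is unreliable because the RNAs are shorter than a sequenced fragment, Mir3096 read 727 and 657, Snora41 301 and 363 and Mir365-2 57.2 and 51.7 FPKM in WT and all were listed at 0 in both Irx5KO libraries. Among all rows tested, 22 small RNA rows were lower and 2 higher in Irx5KO. Small RNA rows held 3.90% and 3.39% of the summed FPKM in WT replicates 1 and 2 and 2.81% and 2.34% in Irx5KO replicates 1 and 2.

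The 12 largest increases held 4 Y-linked genes, 2 small RNA rows and 6 other genes. Fkbp5, which encodes a chaperone of the glucocorticoid receptor, rose from 8.67 ± 1.59 to 69.9 ± 14.8 FPKM (2.87, adjusted p = 4.29e-05). Tsc22d3, the glucocorticoid-induced leucine zipper gene, rose from 39.6 ± 25.5 to 289 ± 65.4 FPKM (2.98, adjusted p = 9.27e-04). Arrdc3, an arrestin-domain gene, rose from 23.2 ± 6.75 to 196 ± 5.49 FPKM (3.05, adjusted p = 4.23e-05), and the serpin gene Serpina3j from 18.6 ± 1.52 to 180 ± 42.3 FPKM (3.19, adjusted p = 2.74e-05). Best2, which encodes a bestrophin anion channel, rose by 3.11 (adjusted p = 4.43e-05), and the transmembrane gene Slitrk6 by 3.04 (1.62e-04 adjusted). The small RNA row Snora24 read 11.4 ± 1.25 FPKM in Irx5KO and 6.77e-05 ± 7.64e-05 FPKM in WT, and Mir466i was listed at 0 in both WT libraries and at 44.04 and 22.7 FPKM in Irx5KO replicates 1 and 2.

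**Figure D3:**
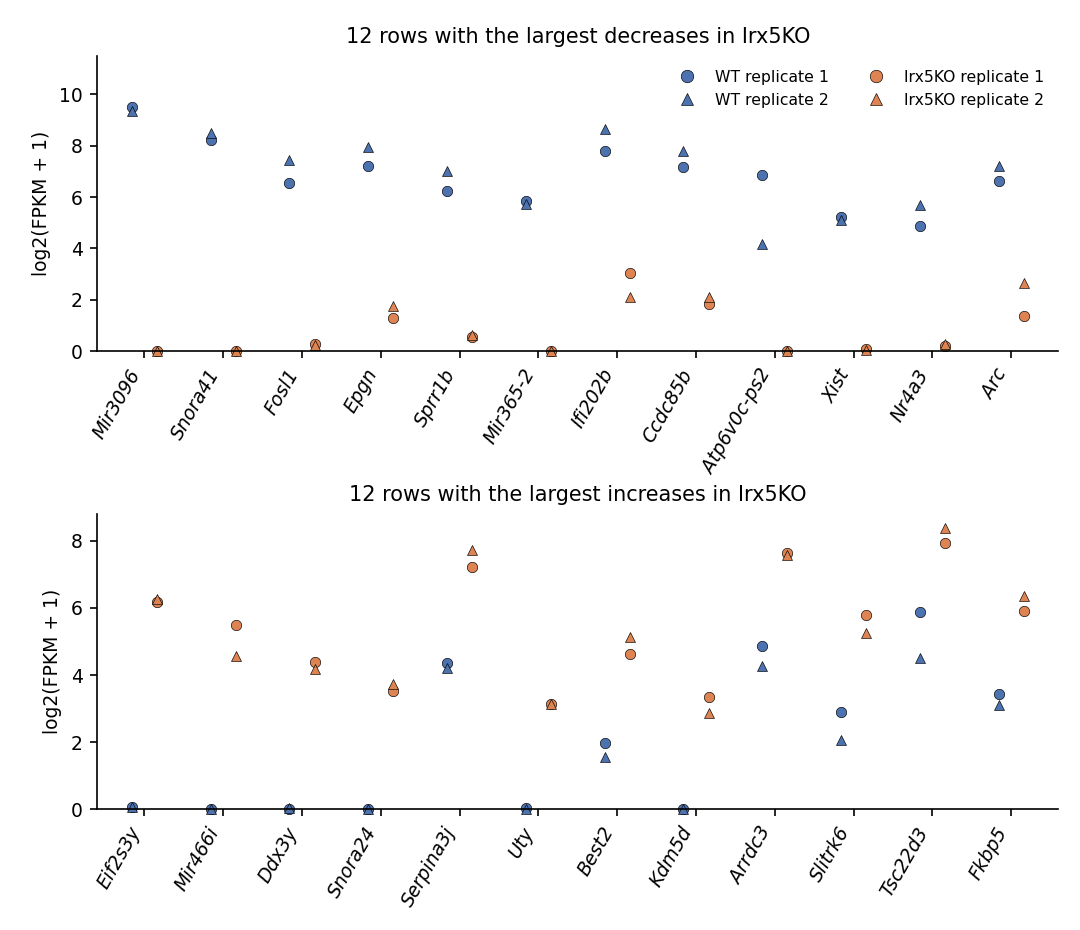
Level as log2(FPKM + 1) in each library for the 12 rows with the largest decreases (top) and the 12 with the largest increases (bottom) in Irx5KO, with circles for replicate 1, triangles for replicate 2, blue for WT and orange for Irx5KO. Fosl1 was at 133 FPKM on average in WT and 0.206 FPKM in Irx5KO, and Fkbp5 at 8.67 and 69.9 FPKM.

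Stress-response genes were lower as groups. Of 20 immediate-early genes, a list that tissue dissociation induces, 18 fell, none rose and 2 did not pass, and all 20 fell when adjusted over the list alone (median -1.88, camera adjusted p = 2.20e-18, adjusted p = 0.579 with an estimated correlation). Nr4a2 fell by 2.94 (adjusted p = 2.63e-05), the growth regulator Myc from 346 ± 8.25 to 42.8 ± 9.55 FPKM (-3.00, adjusted p = 3.81e-05), Maff by 2.74 and Nr4a1 from 833 ± 113 to 38.5 ± 33.1 FPKM (-4.70, adjusted p = 3.59e-04). Of 23 stress and wound keratinocyte genes, 15 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone (median -1.84, camera adjusted p = 4.24e-15, adjusted p = 0.579 with an estimated correlation). They included the receptor ligands Areg (86.3 ± 6.79 to 4.96 ± 0.645 FPKM, adjusted p = 3.61e-06) and Ereg (35.2 ± 6.12 to 2.76 ± 0.847 FPKM, adjusted p = 2.74e-05) and the wound keratin Krt16 (955 ± 403 to 42.0 ± 0.269 FPKM, adjusted p = 2.74e-05). The gene that rose was S100a9, named after its values were seen. The size of the median of the wound list depended on the settings, at -3.39 with a pseudocount of 0.1, -3.21 at a mean of at least 5 FPKM and -0.97 with no filter. Of 11 heat shock genes 8 fell, also adjusted over the list alone, and 5 without Irx5KO replicate 1, led by Dnajb1 (688 ± 0.83 to 85.6 ± 34.3 FPKM) and Hsp90aa1 (309 ± 32.3 to 73.1 ± 2.97 FPKM) (camera adjusted p = 1.36e-08, adjusted p = 0.524 with an estimated correlation). These lists stayed lower under every scaling tried. All 4 samples were enzymatically dissociated by the same stated protocol, and the genotypes differed in sex as above.

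The layers of the epidermis changed unevenly. Of 29 granular and cornified layer genes 17 fell, 3 rose and 9 did not pass (20 and 3 adjusted over the list alone), with a median of -1.32 (camera adjusted p = 1.82e-12, adjusted p = 0.729 with an estimated correlation). The falls were led by genes of the late cornified envelope cluster, Lce1i (23.9 ± 3.74 to 1.47 ± 0.694 FPKM), Lce1d (31.2 ± 7.87 to 2.80 ± 0.828 FPKM), Lce1f and Lce1h, whose near-identical copies can share reads. Tgm3, Rptn and Casp14, all of the same layers and named after their values were seen, rose. Of 14 basal layer genes 4 rose and 4 fell, also adjusted over the list alone, with the keratin Krt14 down from 5009 to 1548 FPKM (-1.69, SE 0.312, adjusted p = 0.00439), the matrix gene Thbs1 at -4.27 (adjusted p = 3.17e-05) and the hemidesmosome gene Dst up by 1.44 (adjusted p = 0.0023). The list did not pass (camera adjusted p = 0.248), and its median of 0.11 turned to -0.19 under median of ratios, with 1 higher and 3 lower without Irx5KO replicate 1. Of 11 spinous layer genes 4 rose and none fell on both adjustments, among them the metallothionein Mt4 (18.9 ± 2.40 to 95.3 ± 3.47 FPKM, adjusted p = 5.97e-05) and the desmosomal cadherins Dsc1 and Dsg1a, without passing as a list (camera adjusted p = 0.564). Sebaceous gland genes were lower as a list, though of 15 only Plin2 (60.7 ± 27.4 to 15.5 ± 2.07 FPKM, adjusted p = 0.00202) fell on both adjustments (camera adjusted p = 2.67e-04, adjusted p = 0.809 with an estimated correlation). This depended on single libraries. Of the list sebaceous gland 11 fell without WT replicate 1 and 7 without Irx5KO replicate 1, and without WT replicate 2 the list did not pass (adjusted p = 0.0886) and its median went from -0.57 to -0.08. Of 5 hair shaft keratins 4 rose, and 5 adjusted over the list alone, led by Krt36 (0.21 ± 0.103 to 2.26 ± 0.0415 FPKM, adjusted p = 4.50e-04) and Krt84 (camera adjusted p = 0.0181, adjusted p = 0.579 with an estimated correlation). Of the 14 hair shaft keratins 9 were below the filter. Krt36 passed the filter through the Irx5KO libraries alone, so the count over the 5 tested genes can lean to increases. With no filter 3 of 14 rose and none fell, with a median of 0.43. Keratin-associated proteins (1 higher and 2 lower of 5, 2 and 2 adjusted over the list alone, camera adjusted p = 0.179) and upper follicle genes (1 lower of 7 on both adjustments, Krt17, camera adjusted p = 0.414) did not pass.

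No DNA repair list passed the test of lists among the rows tested, though single repair genes changed. Of 20 tested genes of homologous recombination and Fanconi anaemia repair 6 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.35, camera adjusted p = 0.251). Rad50, of the MRN complex, went from 4.13 ± 0.532 to 8.78 ± 0.138 FPKM (0.94, adjusted p = 0.00413). Rmi1 rose by 0.78 (adjusted p = 0.00931), Fancb by 0.74 (adjusted p = 0.0099), and the nuclease gene Eme1 fell from 2.18 ± 0.0358 to 1.06 ± 0.0107 FPKM (adjusted p = 0.0159). Scaled by the median of ratios, 3 of the list rose and 2 fell, and 9 rose without WT replicate 1, 3 without WT replicate 2, 1 without Irx5KO replicate 1 and 4 without Irx5KO replicate 2. With no filter on level the list homologous recombination and Fanconi anaemia repair passed (adjusted p = 0.0142), as did the list excision and mismatch repair (adjusted p = 0.04995). There 5 of 38 and 1 of 36 members rose, and the list medians were 0.24 and 0.36. The median of all rows, with which lists are compared, moved from 0.26 to 0.08 in that setting. Brca1, at 0.0961 and 0.222 FPKM in WT and 0.165 and 0.179 FPKM in Irx5KO, was under the expression filter and was not tested. Among 11 genes of end joining 2 rose, Polm and Lig4, on both adjustments (camera adjusted p = 0.554), against 1 under median of ratios, without WT replicate 2 and without Irx5KO replicate 1 and 0 without Irx5KO replicate 2. Among 33 genes of excision and mismatch repair 11 rose and 1 fell on both adjustments, led by Xpc (8.26 ± 1.75 to 18.0 ± 4.06 FPKM, adjusted p = 0.00709) and Xpa (camera adjusted p = 0.207). The number that rose came to 3 under median of ratios and 4 under quantile normalization, and to 19 without WT replicate 1, 2 without Irx5KO replicate 1 and 6 without Irx5KO replicate 2. Of 16 DNA damage checkpoint genes 8 rose and none fell, and 9 rose adjusted over the list alone, among them Etaa1 (1.01 ± 0.0344 to 4.19 ± 0.363 FPKM, adjusted p = 6.02e-04), Rad1 and Hus1 (camera adjusted p = 0.163). The median of ratios left 3 checkpoint genes higher and 1 lower, and 3 were higher without Irx5KO replicate 1 and 4 without Irx5KO replicate 2.

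Targets of p53 split in both directions. In the list p53 target genes, of 23 genes 8 rose and 9 fell, also adjusted over the list alone (median -0.11, camera adjusted p = 0.0191, adjusted p = 0.579 with an estimated correlation), and the median turned to 0.13 in TPM. The counts were 4 and 11 under median of ratios, 5 and 7 without WT replicate 2 and 4 and 7 without Irx5KO replicate 1. The list no longer passed under median of ratios (adjusted p = 0.140), under quantile normalization (adjusted p = 0.157) or without Irx5KO replicate 1 (adjusted p = 0.0601). The cell cycle inhibitor Cdkn1a fell from 613 ± 26.8 to 181 ± 41.0 FPKM (-1.77, adjusted p = 0.00101). So did the polo-like kinase genes Plk2 (75.9 ± 9.84 to 15.03 ± 1.74 FPKM, adjusted p = 7.86e-05) and Plk3 (56.3 ± 7.78 to 6.77 ± 3.53 FPKM, adjusted p = 1.96e-04). The sestrin gene Sesn1 rose from 14.6 ± 2.76 to 69.4 ± 2.41 FPKM (2.18, adjusted p = 1.02e-04) and Trp53inp1 from 15.5 ± 4.14 to 55.6 ± 4.93 FPKM (1.79, adjusted p = 5.33e-04). Trp53 itself was at 37.1 ± 2.04 FPKM in WT and 45.1 ± 3.43 FPKM in Irx5KO (adjusted p = 0.237).

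Mitotic genes were higher at low levels. Of 36 genes of G2/M and mitosis 24 rose, 2 fell and 10 did not pass, with 26 and 2 adjusted over the list alone (median 0.72, camera adjusted p = 0.0107, adjusted p = 0.809 with an estimated correlation). Ccna2 rose from 1.48 ± 0.0833 to 4.29 ± 1.43 FPKM (adjusted p = 0.00569), Hmmr from 0.355 ± 0.142 to 1.52 ± 0.452 FPKM (adjusted p = 0.00727) and the proliferation marker Mki67 from 1.77 ± 0.638 to 3.77 ± 0.603 FPKM (0.80, adjusted p = 0.0173). The log2 fold change of Mki67 did not pass under median of ratios (0.57, adjusted p = 0.0889), under quantile normalization (adjusted p = 0.140) or without Irx5KO replicate 2 (adjusted p = 0.0754). Cks2 fell from 30.8 ± 1.59 to 14.8 ± 4.94 FPKM (adjusted p = 0.00835). The number that rose came to 8 under median of ratios and 4 under quantile normalization, with the median still positive. With no filter 2 of 45 members rose and none fell, with a median of 0.63. The filter also kept genes that reached 1 FPKM in the libraries of 1 genotype alone, such as Hmmr in Irx5KO. The count over the 36 tested genes can therefore lean to increases. The call of the list was lost without WT replicate 1 (11 higher, adjusted p = 0.263) or without Irx5KO replicate 2 (5 higher, adjusted p = 0.230). The list G2/M and mitosis also did not pass with the length and GC correction (22 higher, adjusted p = 0.0592). At a mean of at least 5 FPKM, with 4 higher and 2 lower of 8 members, it did not pass and its mean difference from other genes turned to -0.0301. Genes of G1/S and DNA replication did not move as a list (8 higher and 3 lower of 32, 8 and 2 adjusted over the list alone, camera adjusted p = 0.649). Their counts were 3 higher and 6 lower under median of ratios, 3 and 7 under quantile normalization, 4 and 1 without Irx5KO replicate 1 and 5 and 3 without Irx5KO replicate 2. The helicase subunit Mcm7 was up (8.76 ± 1.40 to 21.5 ± 0.373 FPKM, adjusted p = 0.00148) and Pcna was down (137 ± 15.5 to 67.1 ± 10.1 FPKM, adjusted p = 0.00545). Replication-dependent histone genes, whose RNAs mostly lack poly(A) tails and whose copies can share reads, were lower: 24 of 36 fell, 25 adjusted over the list alone, 15 without Irx5KO replicate 1 and 14 with the length and GC correction, which moved their median from -0.70 to -0.41. Hist1h2bc was at 122.6 ± 3.93 FPKM in WT and 21.4 ± 2.92 FPKM in Irx5KO (camera adjusted p = 1.96e-16, adjusted p = 0.524 with an estimated correlation). Of 12 cell cycle inhibitors 5 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.649), with Cdkn1b up from 16.8 ± 0.321 to 41.0 ± 2.25 FPKM (adjusted p = 9.94e-04) against the fall of Cdkn1a. The inhibitor counts were 3 and 3 under median of ratios, under quantile normalization, without WT replicate 2 and without Irx5KO replicate 2, and 1 and 3 without Irx5KO replicate 1.

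Markers of hair follicle stem cells were mixed. Of 18 bulge genes 8 rose, 3 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.882), and under median of ratios 1 rose and 4 fell. The number that rose came to 4 without WT replicate 1, 1 without Irx5KO replicate 1 and 2 without Irx5KO replicate 2. The stem cell regulators Sox9 (74.5 ± 19.8 to 26.9 ± 5.23 FPKM, adjusted p = 0.00243) and Lhx2 (9.84 ± 0.769 to 21.01 ± 0.559 FPKM, adjusted p = 0.00246) moved in opposite directions. Cd34 (5.92 ± 0.713 and 9.15 ± 1.71 FPKM, adjusted p = 0.0498) and Lgr5 (4.19 ± 2.05 and 7.54 ± 1.34 FPKM, adjusted p = 0.0497) lay just past the threshold. Neither passed under median of ratios (log2 fold change of Cd34 0.28, adjusted p = 0.321, and log2 fold change of Lgr5 0.51, adjusted p = 0.232), without WT replicate 1 (0.101 and 0.159 adjusted) or without Irx5KO replicate 1 (0.419 and 0.145 adjusted), nor did Cd34 without Irx5KO replicate 2 (adjusted p = 0.0769). Neither Krt15 (4059.97 and 5184 FPKM, adjusted p = 0.452) nor Fgf18 (1.74 ± 0.518 and 1.39 ± 0.301 FPKM, adjusted p = 0.446) passed, though the log2 fold change of Krt15 passed under quantile normalization (0.76, adjusted p = 0.0385) and in TPM (0.61, adjusted p = 0.0310). Among 10 genes of the growing follicle 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.649), with 3 higher under median of ratios and without Irx5KO replicate 2. Shh, the signal of the growing hair germ, was at 0.00746 FPKM in Irx5KO replicate 1 and listed at 0 in the other 3 libraries. BMP pathway genes were lower as a list, with 6 of 10 falling and 1 rising (6 and 2 adjusted over the list alone). The target Id3 fell from 512 ± 15.7 to 38.3 ± 8.74 FPKM (-3.73, adjusted p = 1.49e-05), Smad7 by 1.45 and Bmp2 from 27.6 ± 0.0865 to 9.95 ± 0.692 FPKM (camera adjusted p = 7.25e-04, adjusted p = 0.579 with an estimated correlation). The Wnt target Axin2 rose from 9.54 ± 3.26 to 23.8 ± 5.35 FPKM (adjusted p = 0.00571), with 3 of 15 Wnt genes higher and 1 lower on both adjustments (camera adjusted p = 0.878). The Wnt counts were 1 and 1 under median of ratios and without Irx5KO replicate 1, 5 and 0 without WT replicate 1 and 1 and 0 without Irx5KO replicate 2. The Hedgehog receptor genes Smo and Ptch1 rose, on both adjustments, without the list of 5 passing (camera adjusted p = 0.357). Under median of ratios and under quantile normalization 1 Hedgehog gene rose. Of 13 FGF genes 4 rose and 2 fell on both adjustments, against 1 and 2 under median of ratios and 1 and 1 without Irx5KO replicate 1. The feedback phosphatase Dusp6 was down (62.3 ± 29.1 to 11.4 ± 2.44 FPKM, adjusted p = 9.30e-04) and Spry2 was up (14.7 ± 1.55 to 31.7 ± 0.177 FPKM, adjusted p = 0.00231; camera adjusted p = 0.649).

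Cholesterol synthesis genes were lower as a list. Of 17 cholesterol synthesis genes 10 fell and none rose, and 11 fell adjusted over the list alone. They included Insig1 (23.8 ± 6.37 to 2.96 ± 0.344 FPKM, adjusted p = 7.19e-05) (camera adjusted p = 4.51e-09, adjusted p = 0.524 with an estimated correlation). Of 13 circadian genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.278). The clock genes Tef (13.6 ± 1.84 to 47.6 ± 1.66 FPKM, adjusted p = 2.29e-04) and Per3 (1.46 ± 0.129 to 5.92 ± 0.0739 FPKM, adjusted p = 3.90e-04) were higher. Cytosolic ribosomal protein genes passed as a list (camera adjusted p = 3.02e-08, adjusted p = 0.809 with an estimated correlation) though of 78 only Rpl30 fell, and none adjusted over the list alone. Their median of -0.31 turned to 0.14 under quantile normalization, came to -0.02 with the length and GC correction and ranged from -0.51 to -0.10 with 1 library left out. The same holds for 72 nuclear genes of oxidative phosphorylation, with 1 higher and 1 lower, none adjusted over the list alone, and a median of -0.09 that turned to 0.16 in TPM (camera adjusted p = 3.10e-04, adjusted p = 0.809 with an estimated correlation). Its counts were 1 higher and 15 lower under median of ratios, 10 and 1 in TPM and with the length and GC correction, 5 and 0 without WT replicate 1 and 1 and 10 without WT replicate 2. The list oxidative phosphorylation, nuclear-encoded did not pass without WT replicate 1 (adjusted p = 0.141) or without Irx5KO replicate 1 (adjusted p = 0.203). Of 10 interferon response genes 2 rose and 3 fell on both adjustments, with Isg15 lower (camera adjusted p = 0.168). The list interferon response passed as lower without WT replicate 2 (adjusted p = 0.0140), and without WT replicate 1 its counts were 4 higher and 1 lower.

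Other cell types of the suspension showed an unequal pattern. Langerhans cell and macrophage genes were lower as a list, with 4 of 10 falling on both adjustments (camera adjusted p = 2.95e-04, adjusted p = 0.809 with an estimated correlation). The size of this fall depended on single libraries. The list median of -1.12 came to -0.38 without WT replicate 1 and to -0.58 without Irx5KO replicate 1. It came to -1.34 without WT replicate 2 and to -1.31 without Irx5KO replicate 2. The Langerhans cell lectin Cd207 fell from 102 ± 7.19 to 12.8 ± 3.35 FPKM (-2.92, adjusted p = 3.81e-05), Cd68 by 1.21 (adjusted p = 0.00211), and the antigen presentation genes H2-Ab1 and Cd74 fell too. Of 10 T cell genes 2 fell, Il2rb and Xcl1, and 1 adjusted over the list alone (camera adjusted p = 0.163), with a median of 0.03 that turned to -0.24 under median of ratios. The WT libraries differed in these genes. In the list T cell 7 were higher and 1 lower without WT replicate 1 (median 0.59), and 4 were lower and none higher without WT replicate 2 (median -0.55, adjusted p = 2.61e-05). Markers of deeper tissue were mostly under the filter, with 11 of 13 dermal fibroblast, 8 of 9 dermal papilla, 10 of 10 endothelial, 6 of 6 mast cell, 13 of 14 skeletal muscle, 6 of 8 smooth muscle, 7 of 9 adipocyte, 3 of 6 Schwann cell, 7 of 11 melanocyte, 4 of 7 erythroid, 5 of 7 Merkel cell and 9 of 12 inner root sheath genes below it, and these lists were too short to test.

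**Figure D4:**
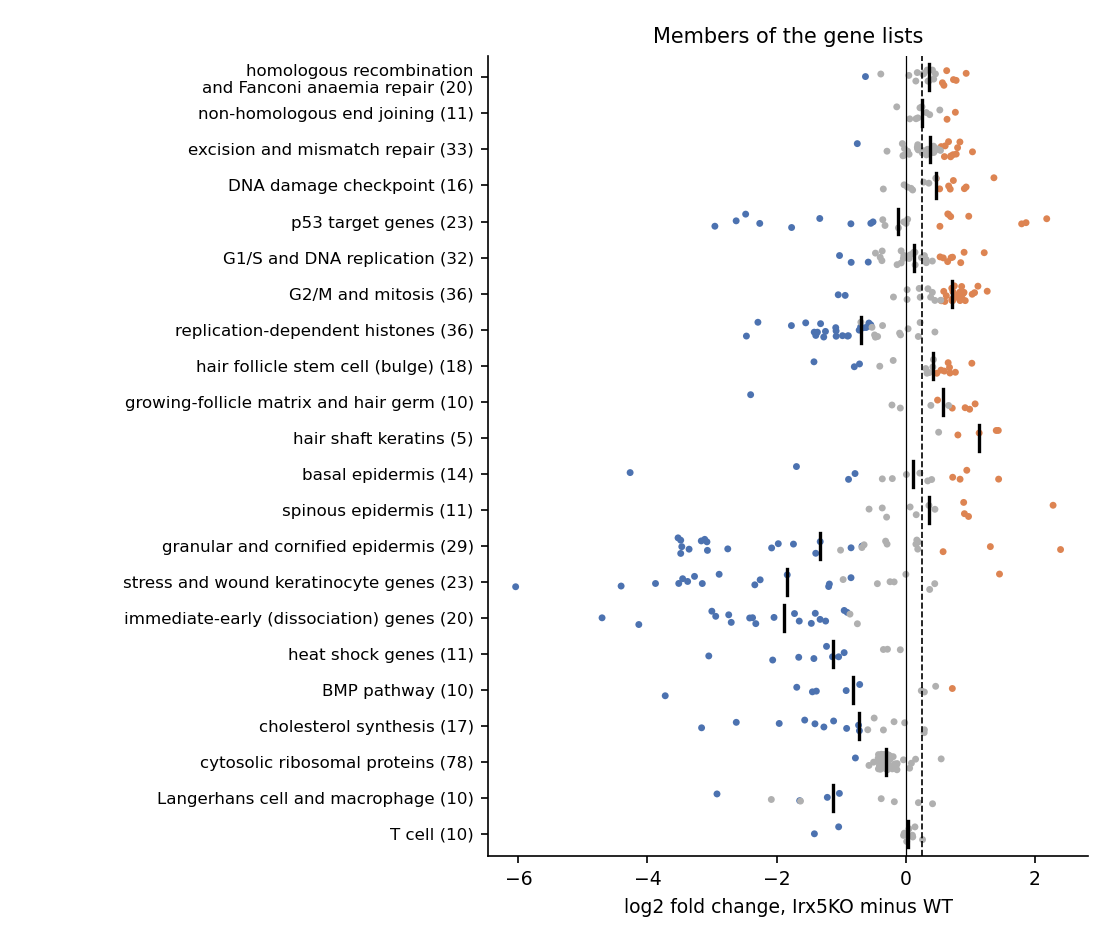
Log2 fold change (Irx5KO minus WT) of each tested member of 22 of the 33 lists, with 1 point per gene, orange for higher, blue for lower and grey for members that did not pass, and the number of members in brackets. Black bars are list medians, -1.88 for immediate-early genes and 0.72 for G2/M and mitosis, and the dashed line is the median of all rows at 0.26.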

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

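No result met the rules for a closer look set in advance, which need larger groups, a second contrast or unused data. The 3 patterns below were weighed instead. The tests of scaling, sex, abundant genes, offset, Xist, length, GC content and the region of Irx5 were chosen after the main results were seen. For length, GC content and the region, the bounds were written before the values of these tests were computed. The bootstrap intervals in this and the later parts resample genes as if they varied independently. The estimated correlation within the immediate-early list was 0.752. The intervals cover the choice of genes and do not measure the spread between mice.

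Immediate-early and wound keratinocyte genes were far lower in Irx5KO than in WT. Scaling does not account for it, since the median of the immediate-early list was at most -1.45 under the 4 other scalings (95% bootstrap interval over genes -2.47 to -0.91). Nor does transcript length or GC content, since removing their trend left a median of -1.87 (-2.49 to -1.29). What stays open is any trait shared by the libraries of a genotype: sex differed with genotype in all 4 libraries (Eif2s3y at 73.3 FPKM on average in Irx5KO), and a difference in handling or in days of preparation would have the same shape. A response of WT keratinocytes to dissociation that is weaker without Irx5 is a biological candidate explanation that these libraries cannot tell from those.

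More genes were higher than lower in Irx5KO. Whether a few abundant genes set the scale of the deposited values stays open. Without the 100 most abundant rows 83.5% of the calls were increases, but that setting also gives the libraries an equal sum of the other rows. The deposited values have no equal sum. An equal sum of all rows (TPM) gave 86.4%. Among scalings to an equal sum, leaving these rows out therefore did not bring the share near to even. Transcript length split the replicates within each genotype (Spearman rho across genes -0.42 for WT replicate 1 minus 2 and 0.42 for Irx5KO replicate 1 minus 2) more than it split the genotypes (0.17). With the trend on length and GC content removed 76.0% of calls were increases, but that correction keeps each library's median and so the overall shift, and a part of length or GC content in it stays open. An overall offset between libraries stays open: scaling by the median of ratios left 43.2% of the calls as increases, but it sets the typical change to 0 by construction, so an offset and a real shift of most genes cannot be told apart.

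Irx5 RNA remained in the knockout at 59.5% of WT, and its neighbour Irx3 was at 42.4%. RNA of the WT libraries in the Irx5KO libraries is argued against by Xist, which was at 0.151% of its WT level where the remaining Irx5 would need far more. A fall shared by the genes within 5 Mb of the locus is argued against by the 54 tested genes there other than Iroquois genes. Their median lay -0.0710 from the rest of chromosome 8 (95% bootstrap interval -0.23 to 0.14), with 18 higher and 6 lower. A fall confined to Irx5 and Irx3 stays open, because Iroquois genes were left out of that median. An allele that leaves part of the Irx5 transcript in place may account for the level, and it was not tested, because values per gene do not resolve exons.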

How the results depend on the processing

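The alternatives were fixed before the data were examined except 1 row per symbol, no small RNA rows, no X and Y genes and the length and GC correction, which were chosen after seeing the data. A change of list is its mean log2 fold change minus that of all other genes. Robust empirical Bayes and the condition on the size of the change were not run on lists. The cause of the differences below was not tested, except that filters change which genes are tested, scaling moves all genes of a library together, and fewer libraries leave fewer degrees of freedom.

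Gene counts moved with the filter, the scaling and the libraries. There were 1289 higher and 712 lower genes with no filter, 1898 higher at a mean of at least 5 FPKM, and 619 and 591 with a log2 change of at least 1. Scaling gave 1226 higher and 1613 lower (median of ratios), 1516 higher (quantile), 5577 higher (TPM) and 4796 higher (without the 100 most abundant rows). Leaving out 1 library gave 1457 to 4048 higher genes, with 1457 without Irx5KO replicate 1 and 1592 without Irx5KO replicate 2, and 725 to 1275 lower genes. In those fits the lone library of a group is assumed to vary like the others. With the replicate number as a block there were 3301 higher and 1166 lower genes. The labels do not say that the numbers pair the mice, and same-numbered libraries did not deviate together (correlation across genes -0.07), so the block marks only a number. Of the 3 ways to split the 4 libraries evenly, the genotypes gave 4200 calls and the others at most 3. The other splits put 1 library of each genotype in each group. The difference between genotypes then adds to their residual spread, so few calls follow by construction and no conclusion is drawn. The genotype split is also the split by sex, and 3 splits are too few for a share under 0.05.

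Irx5 stayed lower throughout, at -0.48 in TPM, where it missed the threshold, and at -0.73 to -0.66 with 1 library left out. The log2 fold change of Trp53, which passed in TPM (0.52) and without the 100 most abundant rows (0.43), turned to -0.0256 under median of ratios, and the log2 fold change of Fgf18 to 0.0394 with the length and GC correction, neither past the threshold there.

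The 2 lists higher came to 4 with no filter, 0 at a mean of at least 5 FPKM, 1 with the length and GC correction, 1 to 2 with 1 library left out (1 without WT replicate 1 or Irx5KO replicate 2), 0 with an estimated correlation and 0 with fry, and the 12 lower to 0 and 0 with the last 2. Homologous recombination and Fanconi repair passed with no filter (0.13, adjusted p = 0.0142), as did the list excision and mismatch repair (0.22). The list G2/M and mitosis turned to -0.0301 and the list G1/S and DNA replication to 0.0337 at a mean of at least 5 FPKM, where the list growing-follicle matrix and hair germ turned to -0.0743. G2/M missed the threshold at 0.36 with the length and GC correction, at 0.19 to 0.60 with 1 library left out (without WT replicate 1 and without Irx5KO replicate 2), and at its unchanged 0.40 with an estimated correlation and fry. The p53 list missed it at -0.48 (median of ratios), -0.36 (quantile), -0.53 to -0.39 with 1 library left out (without Irx5KO replicate 1), and at its unchanged -0.46 with an estimated correlation, ranks and fry. The bulge list turned to -0.11 without WT replicate 1 and ranged from -0.11 to 0.20 with 1 library left out. Under quantile normalization the list Wnt pathway turned to -0.0137, the list oxidative phosphorylation, nuclear-encoded to 0.0771, ribosomal proteins to 0.14 and the upper follicle to 0.16. The Wnt list also turned to -0.00352 with the length and GC correction and ranged from -0.0705 to 0.12 with 1 library left out, and the T cell list, which passed at -0.81 without WT replicate 2, turned to 0.11 without WT replicate 1 (range -0.81 to 0.11).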

Other observations

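The lists of this part were chosen after the main results were seen. Their predictions were written before the members' values were looked at, except that Bnip3 had already been seen among the increases when it was put on the list of FoxO targets.

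Genes higher in Irx5KO included Fkbp5, Tsc22d3, Arrdc3 and Sesn1, which are known targets of the glucocorticoid receptor or of FoxO factors, and 2 hypotheses were tested on further targets. The further glucocorticoid receptor targets did not rise as a group. Of 10 further targets none rose and 8 fell, and their median lay -2.03 from that of all genes (95% bootstrap interval -2.59 to -0.85; camera adjusted p = 4.55e-09 over the 3 lists of this part, adjusted p = 0.290 with an estimated correlation). The metallothionein genes Mt1 (1648 ± 428 to 294 ± 89.5 FPKM) and Mt2 (1539 ± 253 to 336 ± 114 FPKM), the feedback inhibitor Errfi1 (184 ± 31.1 to 39.6 ± 8.10 FPKM) and Nfkbia (662 ± 56.8 to 120 ± 39.6 FPKM) fell, and Sgk1 read 104 ± 22.5 FPKM in WT and 104 ± 20.7 FPKM in Irx5KO. Several of these genes also belong to the acute stress response, so their fall does not settle whether glucocorticoid signalling differed. Read apart from this list, Glul (2.06), Txnip (2.56), Ddit4 (1.86) and the receptor gene Nr3c1 (0.63) were higher in Irx5KO.

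Targets of FoxO factors, which are active when growth factor signalling is low, leaned higher without deciding the question. Of 13 further targets 7 rose and 2 fell, and their median lay 0.33 above that of all genes (95% bootstrap interval -0.10 to 0.78; camera adjusted p = 0.144, adjusted p = 0.290 with an estimated correlation). Without Bnip3, seen beforehand, the 12 others lay 0.23 above all genes. The mitophagy receptor gene Bnip3 rose from 11.48 ± 0.543 to 48.9 ± 5.64 FPKM, the kinase inhibitor Pik3ip1 from 10.6 ± 3.56 to 37.5 ± 0.458 FPKM, catalase (Cat) from 32.6 ± 0.718 to 74.6 ± 10.9 FPKM and Ccng2 from 9.65 ± 0.428 to 20.8 ± 1.79 FPKM, while Irs2 fell from 22.96 ± 9.58 to 7.33 ± 0.0427 FPKM and Sesn3 from 3.90 ± 0.189 to 2.49 ± 0.191 FPKM.

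X-linked genes that escape X inactivation, expected higher in females, leaned the way of the sex difference that Xist and the Y-linked genes show. As a group they did not pass. Of 345 X genes other than Xist 97 were higher and 17 lower, and the 28.1% higher compares with 26.8% on the autosomes. Of 7 tested escape genes Ddx3x fell in Irx5KO from 239 ± 72.8 to 80.3 ± 2.93 FPKM (adjusted p = 0.00212), 2 rose (Ftx and 5530601H04Rik) and 4 did not pass. Of those 4, Eif2s3x (-0.32), Kdm5c (-0.30) and Kdm6a (-0.24) were lower in Irx5KO and Pbdc1 (0.13) higher. The median of the 7 lay -0.55 from that of other X genes, past the -0.3 set in advance for a sex difference, but its 95% bootstrap interval of -0.66 to 0.25 includes 0 (camera adjusted p = 0.144).

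Levels of housekeeping genes moved unequally, as values with no explanation. Actb read 1801 and 2121 FPKM in WT and 398 and 535 FPKM in Irx5KO (adjusted p = 9.73e-04), and Actg1 3888 and 4996 against 744 and 1041 FPKM (adjusted p = 0.0012). Gapdh read 387 and 317 against 239 and 290.2 FPKM (adjusted p = 0.183) and Hprt 41.9 and 47.8 against 37.8 and 37.3 FPKM (adjusted p = 0.280).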
